A study of Mus musculus with 9 samples.

How the data were processed

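RNA sequencing was performed on primary mouse microglia, the resident macrophages of the brain, in 9 libraries from 3 treatment groups of 3. Per the labels' protocols, glia were cultured from whole brains of 3-day-old ICR pups, microglia were shaken off the mixed cultures, plated for 24 h and then treated for 4 h. The R848 group received 1 µM R848, the IFN-α group received 100 U/ml IFN-α, and the combined group received both. Ribosomal RNA was removed before directional libraries were made, in a kit that keeps the strand of each transcript, and paired-end reads of 101 cycles were sequenced on an Illumina HiSeq instrument whose model is given differently in separate labels. A control group named in the design text is not analysed here.

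The authors deposited read counts per gene for each library, with an unstranded, a forward-strand and a reverse-strand count in each row. Per the submitters' processing notes, the upstream tools were CASAVA 1.8.2, Trimmomatic 0.33, STAR 2.5.1 and DESeq2, with the mouse genome build mm10. The annotation behind the counts is not given in the sources used here. The deposited counts are whole numbers and had not been normalized. Reverse-strand counts exceeded forward-strand counts in every library, with forward-strand counts making up 1.32%, 1.31% and 1.22% of both strands on average in the R848, IFN-α and combined groups, so the reverse-strand column was used throughout. Reads that mapped to several places are not counted by STAR, so genes with near-identical copies can be undercounted and are named as uncertain.

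Each file held 24411 gene rows, and the summary rows that name no gene were kept out of library totals and tests. Reads in no annotated gene on that strand made up 41.9 ± 2.53% (SD, n = 3) of read pairs in the R848 group, 41.8 ± 0.426% in the IFN-α group and 40.6 ± 0.943% in the combined group. Unmapped read pairs made up 22.9 ± 3.25%, 23.0 ± 0.976% and 23.3 ± 2.16%, and multi-mapping ones 7.77 ± 0.485%, 8.26 ± 0.278% and 8.20 ± 0.281%. The ribosomal transcript Rn45s held 17.9 ± 3.70%, 19.5 ± 5.70% and 18.1 ± 4.12% of gene counts. No mitochondrial gene rows were among those given.

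Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total count 15, by group), which left 11002 genes. Library totals were scaled with TMM factors, and a model of group means was fitted to all 9 libraries with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, using robust dispersion and quasi-likelihood estimation. The biological coefficient of variation was 0.0955. Each pair of groups was compared with the quasi-likelihood F test, and all 3 groups were compared together with the same test. A gene was called where the Benjamini-Hochberg adjusted p, over all genes tested, was under 0.05. A gene was called higher or lower in the combined group than in both single-agent groups where the larger of its p-values against R848 and IFN-α, with the same sign in both, passed that threshold after adjustment. CPM values come from edgeR's cpm function on the TMM-scaled totals, and fold changes are from the fitted model. Errors are SE for log2 fold changes and SD for CPM. The SE of a gene is its absolute log2 fold change divided by the square root of its F statistic, so it is approximate.

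Before the data were examined, 25 gene lists and the rule for named genes were fixed. The 23 lists with at least 4 tested members were tested with camera, a competitive test of a list against all other genes, at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the data. The rule named, per comparison, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those called, with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups. Predicted and clone-named genes were left out. Per list it named up to 4 called members with the largest absolute change, with no filter on level or overlap. For the genes above or below both single agents it named the 10 with the largest value of the smaller of both changes, under the level, overlap and name filters. Isg15, Ifnb1, Tnf, Il1b, Il6, Il12b, Cxcl10, Ccl5, Nos2, Tlr7, Ifnar1, P2ry12, Tmem119 and Cx3cr1 were given whatever they showed. Positions are from GENCODE mouse release 21 on GRCm38, the assembly that mm10 names.

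The labels do not say whether the replicates came from separate cultures or litters, so p-values measure only the spread between these libraries, which may be technical. Every replicate pair differed by more than sampling noise over genes with at least 20 summed counts, with chi-square per degree of freedom from 1.94 to 12.1. Rn45s was among those genes, and its share ran from 16.0% to 26.1% within the IFN-α group, so it may hold part of that excess. The value without Rn45s was not computed. Each library counted as 1 sample. For a gene at 0 in all libraries of a group, a bound was computed against a floor of 3 counts over that group. For a group with 1 to 3 counts, the ratio is given with an exact 95% interval. Intervals and floors cover counting error only. A count of 0 in a single library allowed 0.603 to 1.30 CPM.

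The procedure was tested on simulated counts in which 200 genes had known changes, over 10 draws per comparison. For the combined group against R848, where a median of 10868.5 genes were tested, 34.2% of genes changed 1.41-fold, 77.0% of those changed 2-fold and 96.9% of those changed 4-fold were recovered, and 6.01% of calls were false. The same shares were 31.6%, 75.9%, 97.7% and 6.57% for the combined group against IFN-α (10880 genes), and 32.6%, 78.9%, 96.9% and 6.31% for R848 against IFN-α (10842 genes). Alternatives covered other scalings, filters, the unstranded column, DESeq2 1.42.0 and limma-voom, fits of only the groups compared, the replicate number as a block, an estimated inter-gene correlation and leaving out each library in turn. After the data were seen, library totals without TMM factors, Rn45s left out, thinning to equal depth and leaving out a pair of libraries together were added. That pair was R848 replicate 1, which stood apart from its group on principal component 3 (28.6 against -11.9 and -17.5, with 4.04% of the variance), and combined replicate 3, the deepest library.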

Results

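Microglial preparations treated with R848, IFN-α or both were compared after 4 h, in 3 libraries per group. The libraries also held transcripts of astrocyte markers such as Gfap and Aqp4. The changes below are therefore those of the whole preparation and cannot be assigned to a cell type. R848, or resiquimod, is a small-molecule agonist of the endosomal receptor TLR7 in mice, and IFN-α is a type I interferon that signals through a receptor containing Ifnar1. The comparisons address what each agent did relative to the other and what each added in the presence of the other. No effect against untreated cells was measured here, and no test of additivity could be made. Gene counts per library ranged from 2817772 to 3298567 in the R848 group, from 2505941 to 2852960 in the IFN-α group and from 2795385 to 6005578 in the combined group, whose replicate 3 was the deepest library.

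The libraries grouped by treatment. The leading principal components of log2 CPM held 53.4% and 30.2% of the variance, the correlation of log2 CPM across genes was at least 0.967 within groups, and between groups it ranged from 0.819 to 0.902. Of 11002 genes tested, 5534 differed among the 3 groups (edgeR quasi-likelihood F test, adjusted p under 0.05).

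**Figure D1:**
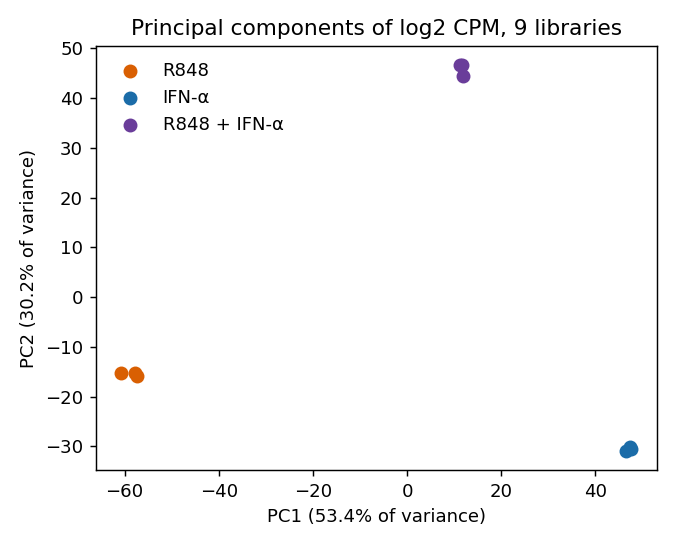
Each point is 1 library, placed by its score on the first principal component (horizontal, 53.4% of variance) and the second (vertical, 30.2% of variance) of log2 CPM, and coloured by treatment. The 3 libraries of each group lie together and the 3 groups lie apart.

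R848 and IFN-α alone gave distinct cytokine and interferon-response profiles. Il1b, which encodes the pro-inflammatory cytokine IL-1β, reached 5688 ± 401 CPM (mean ± SD, n = 3) with R848 and 4.97 ± 2.10 CPM with IFN-α, and Tnf reached 4649 ± 496 and 83.6 ± 14.2 CPM. Isg15, a ubiquitin-like protein induced by interferon, was at 22.2 ± 0.520 CPM with R848 and 624 ± 21.8 CPM with IFN-α. Tlr7, the receptor for R848, was at 114 ± 14.9 and 617 ± 32.3 CPM, and Ifnar1 at 334 ± 10.4 and 142 ± 8.77 CPM. The test called 4119 genes between the single agents, 2024 higher and 2095 lower with R848, of which 760 and 1056 differed at least 2-fold.

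Cytokine and chemokine genes were mostly higher with R848. Of 18 genes tested in the pro-inflammatory cytokine list, 15 were higher and 3 lower (median log2 fold change 2.95). The split was the same adjusted over the list alone. That list also holds the anti-inflammatory genes Il10 and Il1rn. Of 21 chemokine genes 15 were higher and 5 lower (median 1.66). Il12b, encoding the p40 subunit shared by IL-12 and IL-23, had 248 ± 28.5 CPM with R848 and no count in any IFN-α library, which makes it at least 702-fold higher with R848 against a floor of 3 counts over the group. Cxcl2, which encodes a neutrophil-attracting chemokine, was at 3929 ± 161 CPM with R848 and 1.86 ± 0.342 CPM with IFN-α. The log2 fold change ± SE was 10.56 ± 0.17 for the related Cxcl1, 10.19 ± 0.15 for Il1b, 8.43 ± 0.12 for Il1a, 3.20 ± 0.14 for Il6 and 5.79 ± 0.12 for Tnf. Ccl5, a T cell chemokine, was higher with R848 by 3.81 ± 0.17, while Cxcl10, an interferon-responsive chemokine, was lower, at -2.56 ± 0.11. The growth factor genes Csf2 and Csf3 had 1 and 2 counts in all IFN-α libraries together, giving ratios of 211-fold (95% counting interval 37.6 to 8386) and 132-fold (95% counting interval 36.1 to 1092). Cxcl3 was higher with R848 by 7.98 ± 0.28. Among the genes of this paragraph the largest adjusted p was 4.76e-13, for Csf2.

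NF-κB pathway and feedback genes and oxidative-response genes were also higher with R848. In the NF-κB list 20 of 22 members were higher and none lower (median 2.08), including Traf1 (5.48 ± 0.20), Tnfaip2 (5.27 ± 0.12) and the inhibitor-like regulator Nfkbiz (4.47 ± 0.099). In the oxidative and nitric oxide list 15 of 19 were higher and 1 lower (median 2.02), including the prostaglandin synthase gene Ptges (6.08 ± 0.13), the cystine transporter Slc7a11 (4.69 ± 0.12) and Srxn1 (3.38 ± 0.11). Nos2, the inducible nitric oxide synthase, had 173 counts over the R848 libraries and 3 over the IFN-α libraries, a ratio of 49.0-fold (95% counting interval 16.5 to 239.8). Nlrp3, a sensor of the inflammasome, was higher with R848 (5.37 ± 0.14). Adora2b, an adenosine receptor gene, had 3 counts over the IFN-α libraries, a ratio of 115-fold (95% counting interval 39.1 to 561), and Spic, a macrophage transcription factor with no count there, was at least 15.4-fold higher with R848.

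All 35 interferon-stimulated genes were lower with R848 than with IFN-α (median log2 fold change -4.76). Cmpk2, Rsad2 (viperin, an antiviral enzyme), Ifit2 and Mx1 differed by -7.04 ± 0.11, -6.74 ± 0.11, -6.71 ± 0.12 and -6.29 ± 0.12. Of 19 MHC class I presentation genes 14 were lower and 1 higher with R848 (median -1.46), led by the transactivator Nlrc5 (-3.83 ± 0.10), the peptide transporter subunit Tap1 (-3.70 ± 0.12) and the immunoproteasome subunit Psmb9 (-3.40 ± 0.12). Slfn1, Pydc4 and Trim30b had no count in any R848 library and were at least 34.6-, 40.7- and 16.9-fold lower there. Klrk1, with 1 count over the R848 libraries, gave an IFN-α to R848 ratio of 512-fold (95% counting interval 91.4 to 20277), and Pydc3, with 2, gave 183-fold (95% counting interval 50.1 to 1514). Tnfsf10, encoding the death ligand TRAIL, differed by -7.52 ± 0.16 and Ifit1bl1 by -8.45 ± 0.17. Slfn1, Pydc3, Pydc4 and Trim30b belong to families with close copies, so their counts are uncertain.

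Homeostatic microglia genes were lower with R848 in 14 of 22 and higher in 4 (median -0.64, camera adjusted p = 0.00533, or adjusted p = 0.124 with an estimated correlation). The purinergic receptors P2ry13 and P2ry12 differed by -6.86 ± 0.21 and -4.06 ± 0.25, while Gpr84 (5.90 ± 0.15) and Cx3cr1, the fractalkine receptor (0.94 ± 0.11), were higher. Tmem119 was at 3.81 ± 0.282 and 2.87 ± 1.18 CPM, a difference that did not pass the test (adjusted p = 0.542). Glycolysis and hypoxia genes were higher in 13 of 21 and lower in 2 (median 0.55, adjusted p = 0.00533, or adjusted p = 0.0998 with an estimated correlation), among them the lactate exporter Slc16a3 (2.58 ± 0.12) and the glucose transporter Slc2a1 (1.93 ± 0.12). Of 26 cholesterol genes 16 were higher and 4 lower, with adjusted p = 0.0504 for the list. It passed in 10 alternatives (adjusted p from 3.27e-04 to 0.04999). Of 29 inflammasome and cell death genes 7 were higher and 17 lower, with adjusted p = 0.0662. That list passed with no low-count filter (0.00488) and without IFN-α replicate 1, 2 or 3 (0.0434, 0.0349 and 0.0402).

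In camera tests of R848 against IFN-α, 8 of 23 lists passed, 5 up and 3 down, and 6 passed with an estimated correlation: interferon-stimulated genes, cytokines, chemokines, NF-κB, MHC class I and the oxidative list. Other lists did not pass. The list named interferon genes also holds their receptors and signalling genes. Its genes encoding interferons, Ifnb1, Ifna1, Ifna2, Ifna4, Ifna5 and Ifng, were too low to be tested in any comparison. The higher and lower counts were 8 and 8 of 21 for Toll-like receptors, 7 and 7 of 18 for interferon genes, 5 and 2 of 9 for MHC class II and costimulation, 5 and 11 of 21 for disease-associated microglia, 0 and 4 of 22 for oxidative phosphorylation, 1 and 3 of 15 for the cell cycle, 9 and 8 of 21 for immediate early genes, 5 and 0 of 16 for the unfolded protein response, and 7 and 6 of 17 for phagocytosis. Markers of other cell types showed 2 higher and 4 lower of 11 for astrocytes, 0 and 3 of 10 for oligodendrocytes, 1 and 1 of 6 for neurons and 2 and 0 of 11 for fibroblasts. The calls of Sox10, Mog, Stmn2, Dcx, Pdgfrb and Dcn among these each ended in at least 1 alternative. Adjusted over the list alone, the higher and lower counts were the same except 20 and 1 for NF-κB, 9 and 8 for Toll-like receptors, 8 and 7 for interferon genes, 1 and 16 for MHC class I, 5 and 3 for MHC class II and costimulation, 16 and 1 for the oxidative list, 10 and 17 for cell death, 5 and 12 for disease-associated microglia, 14 and 2 for glycolysis, 0 and 3 for oxidative phosphorylation and 9 and 9 for immediate early genes. Median and test differed in sign for interferon genes (median 0.025, test down), the cell cycle (median 0.10, test down) and phagocytosis (median 0.25, mean -0.29, test down). Of 9 endothelial markers listed 3 were tested, since Pecam1, Cldn5, Tek, Tie1, Emcn and Esam had too few counts. Of the 3, Kdr (-5.00 ± 0.35) and Flt1 (-2.83 ± 0.34) were lower. Of 14 other leukocyte markers listed only S100a8, a neutrophil gene, was tested, and it was higher (1.16 ± 0.25). S100a9 and Ly6g were not tested. These few genes do not show a change of endothelial cells or neutrophils.

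**Figure D2:**
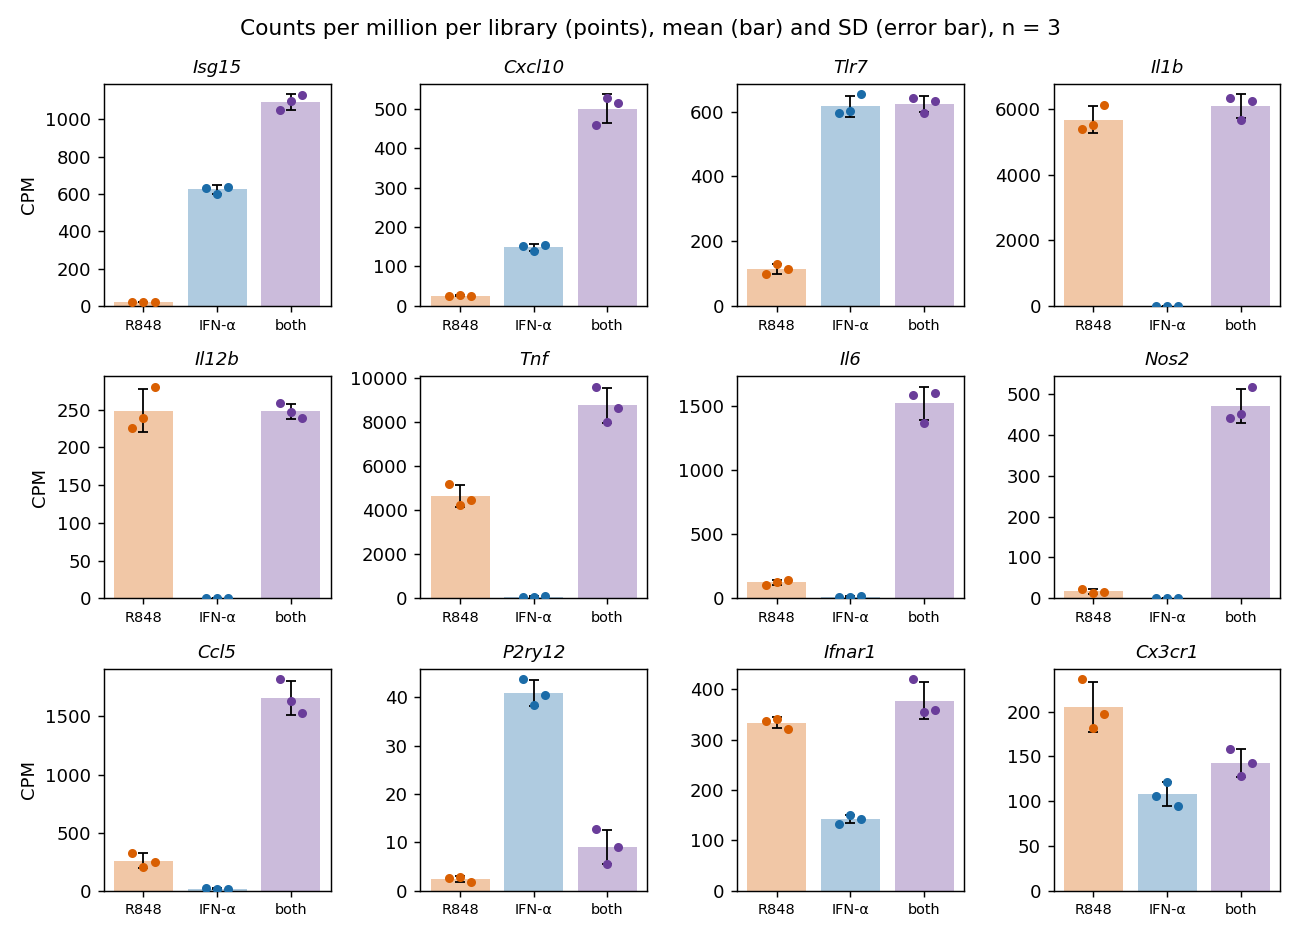
Each panel shows 1 gene, with CPM on a linear vertical axis that starts at 0, points for the 3 libraries of each group, bars for the mean and error bars for the SD (n = 3). Il1b was at 4.97 ± 2.10 CPM with IFN-α alone, Isg15 at 22.2 ± 0.520 CPM with R848 alone, and Il6, Nos2 and Ccl5 were highest with both agents, at 1517 ± 129.5, 469 ± 41.6 and 1659 ± 149 CPM.

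Adding IFN-α to R848 raised the interferon-stimulated genes and several inflammatory genes. Isg15 went from 22.2 ± 0.520 CPM with R848 to 1094 ± 41.1 CPM with both, a 49.2-fold difference. Il6 went from 127 ± 18.8 to 1517 ± 129.5 CPM (3.58 ± 0.10 as log2 fold change ± SE), Nos2 from 17.2 ± 5.50 to 469 ± 41.6 CPM (27.2-fold) and Ccl5 from 259.8 ± 64.2 to 1659 ± 149 CPM (6.38-fold). Il1b was at 6092 ± 370.3 CPM with both agents, and its difference from R848 alone did not pass the test (0.099 ± 0.09, adjusted p = 0.419). Between the combined group and R848 alone 3947 genes were called, 2112 higher and 1835 lower, with 977 and 407 differing at least 2-fold.

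All 35 interferon-stimulated genes were higher with both agents than with R848 (median log2 fold change 5.15), among them Cmpk2 (7.65 ± 0.11), Rsad2 (7.56 ± 0.11), Ifit2 (7.18 ± 0.12) and Mx1 (6.91 ± 0.12). MHC class I presentation genes were higher in 17 of 19 and lower in none (median 1.68), with Tap1 at 4.38 ± 0.12, Nlrc5 at 4.25 ± 0.10, Psmb9 at 3.15 ± 0.12 and H2-T23 at 3.11 ± 0.10. Slfn1 and Pydc4, at 0 with R848, were at least 95.0- and 24.2-fold higher. Klrk1 rose 229-fold (95% counting interval 40.7 to 9078). The serine protease inhibitor genes Serpina3g (8.13 ± 0.21) and Serpina3f (7.81 ± 0.18) and the Schlafen gene Slfn4 (7.07 ± 0.19) were also higher. Serpina3f and Serpina3g are near-identical copies, and these counts are uncertain. Tlr7 rose by 2.46 ± 0.096, with Tlr3 (4.85 ± 0.12), Tlr9 (3.07 ± 0.30) and the adaptor Myd88 (1.64 ± 0.092), in a list with 8 of 21 members higher and 6 lower.

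Of 18 cytokine genes 12 were higher and 1 lower (median 1.12). The adjustment over the list alone gave 12 and 2. Il27 rose by 4.29 ± 0.14, the receptor antagonist gene Il1rn by 3.39 ± 0.09, Tnfsf15 by 3.34 ± 0.12 and Tnf by 0.92 ± 0.094. Il12b was at 248 ± 9.70 CPM against 248 ± 28.5 CPM with R848 (adjusted p = 0.977). It was lower with library totals alone (-0.40, adjusted p = 0.0119). Ifnb1, encoding IFN-β, was too sparse to test, with 1 count over the R848 libraries and 13 over the combined ones.

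Chemokine genes moved both ways, with 13 of 21 higher and 5 lower (median 0.68). Cxcl9 rose by 9.19 ± 0.16, Ccl12 by 6.38 ± 0.13, Ccl8 by 4.55 ± 0.34 and Cxcl10 by 4.31 ± 0.11. Cxcl3 fell from 129 ± 13.8 to 3.51 ± 0.711 CPM (-5.22 ± 0.20) and Cxcl5 fell from 11.8 ± 2.46 CPM with R848, at -2.82 ± 0.39. In the oxidative and nitric oxide list 5 of 19 members rose, Nos2 and the prostaglandin synthase Ptgs2 (1.85 ± 0.12) among them, and 10 fell, including the glutathione synthesis gene Gclm (-1.58 ± 0.11) and haem oxygenase Hmox1 (-1.52 ± 0.14). That list's median was -0.31, its mean 0.088, and it did not pass camera (adjusted p = 0.907). Treml4, a myeloid receptor gene, was at -5.11 ± 0.36, and Peli3, Cd300e, Sla, Chst10 and Spic had log2 fold changes of -3.57, -3.09, -2.99, -2.96 and -2.88. Those of Adm, encoding the vasodilator adrenomedullin, and B3gnt7 were -2.87 and -2.73. Among the genes of this paragraph that fell, the largest adjusted p was 1.40e-04, for Spic.

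Cholesterol synthesis genes were lower in 18 of 26 and higher in 2 (median -0.62, adjusted p = 0.00348, or 0.0446 as the adjusted p with an estimated correlation). Mvd, an enzyme of the mevalonate pathway, had a log2 fold change of -1.90 ± 0.24 and Hsd17b7 of -1.08 ± 0.21, whereas the members that rose were Ch25h (1.72 ± 0.09), which makes 25-hydroxycholesterol, and the sterol exporter Abcg1 (1.53 ± 0.22). Inflammasome and cell death genes were higher in 21 of 29 and lower in 3 (median 0.81), with Tnfsf10 at 6.98 ± 0.16, the necroptosis effector Mlkl at 4.45 ± 0.31, Daxx at 4.02 ± 0.13 and the DNA sensor Aim2 at 3.23 ± 0.12. Homeostatic genes were higher in 10 of 22 and lower in 4 and did not pass camera (adjusted p = 0.722), with P2ry13 (3.59 ± 0.30), P2ry12 (1.92 ± 0.32) and Mertk (2.44 ± 0.19) higher and Tmem119 (-2.84 ± 0.60) and Cx3cr1 (-0.52 ± 0.11) lower. Tmem119 had 5 counts over the combined libraries. Ifnar1 was at 377 ± 36.7 CPM and did not pass the test (adjusted p = 0.121). It did pass without R848 replicate 1 and combined replicate 3 (0.24, adjusted p = 0.0342).

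Astrocyte markers were higher in 10 of 11 and lower in none (median 0.77), without passing camera (adjusted p = 0.136). Only 5 were higher with upper-quartile factors and 4 with library totals alone. The list passed camera with no low-count filter (adjusted p = 2.43e-04), with library totals alone (0.0439) and without R848 replicate 1 and combined replicate 3 together (0.0299). The water channel Aqp4 was at 494 ± 123 CPM with R848 and 1048 ± 157 CPM with both, and Gfap was at 897 ± 42.2 and 1418 ± 363 CPM. Oligodendrocyte markers were higher in 1 of 10 (Cnp, 1.37 ± 0.10, itself interferon-responsive) and fibroblast markers in 2 of 11 (Col1a2 and Postn, calls that ended with library totals alone, at adjusted p = 0.232 and 0.217). The Col1a2 call also ended in other alternatives, among them the DESeq2 test (adjusted p = 0.0944). Without combined replicate 3 the log2 fold change of Col1a2 was 0.26 (adjusted p = 0.499). Of 6 neuron markers 1 was higher (Map2, 0.39 ± 0.13), and its sign turned with library totals without TMM factors. The only 3 endothelial markers tested of 9 listed, Flt1 (2.49 ± 0.35), Kdr (2.44 ± 0.48) and Cdh5 (0.99 ± 0.18), were higher. S100a8 was at -0.52 ± 0.22 (adjusted p = 0.0694).

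Of 23 lists 10 passed camera in this comparison, 9 up and 1 down. With an estimated correlation 6 passed: interferon-stimulated genes, cytokines, chemokines, MHC class I, inflammasome and cell death, and cholesterol synthesis. The others were interferon genes (12 higher and 3 lower of 18, led by Irf8 at 3.11 ± 0.11), MHC class II and costimulation (4 and 1 of 9, led by Cd86 at 2.88 ± 0.12) and phagocytosis (9 and 3 of 17, led by Fcgr1 at 5.61 ± 0.12), each with adjusted p = 0.0537 with an estimated correlation, and immediate early genes (11 and 2 of 21, led by Zfp36 at 2.14 ± 0.16), with adjusted p = 0.566. The immediate early call also ended with a stricter filter (0.0564) and without R848 replicate 3 (0.0533) or combined replicate 1 (0.0540). No gene encoding an interferon was tested in the interferon genes list. Lists that did not pass had 12 higher and 4 lower of 22 for NF-κB, 6 and 6 of 21 for disease-associated microglia, 5 and 12 of 21 for glycolysis, 1 and 0 of 22 for oxidative phosphorylation, 3 and 4 of 15 for the cell cycle and 3 and 2 of 16 for the unfolded protein response. With no low-count filter NF-κB (adjusted p = 0.0188) and glycolysis (0.0248) passed, and 14 lists in all. Adjusted over the list alone, the higher and lower counts were the same except 12 and 2 for cytokines, 13 and 6 for chemokines, 14 and 4 for NF-κB, 8 and 7 for Toll-like receptors, 12 and 4 for interferon genes, 10 and 5 for homeostatic genes, 5 and 2 for the unfolded protein response, 9 and 4 for phagocytosis and 0 and 1 for S100a8 as the sole leukocyte marker tested. Median and test differed in sign for Toll-like receptors (median -0.05, test up), disease-associated microglia (0.044, down), oxidative phosphorylation (0.056, down) and the unfolded protein response (0.002, down), and for the oxidative list the mean was positive with median and test down. The higher share of calls depended on the scaling: it was 53.5% with TMM, 37.5% with upper-quartile factors and 19.1% with library totals alone, settings that moved the median of all genes by -0.13 and -0.39. DESeq2 called 1194 genes lower where edgeR called 1835.

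**Figure D3:**
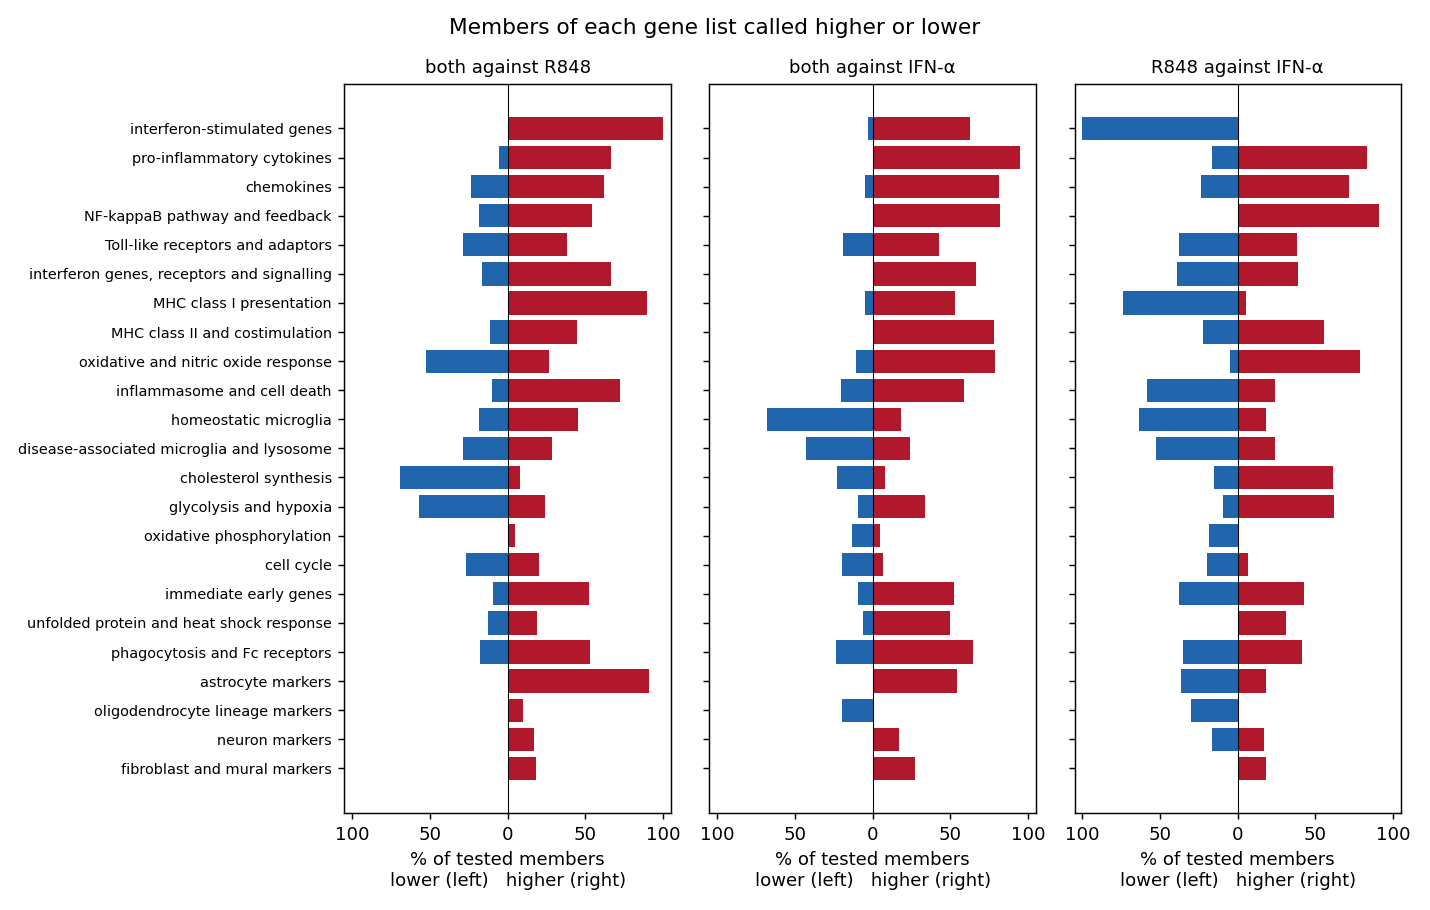
For each gene list (rows) and comparison (panels), bars to the right give the percentage of tested members called higher and bars to the left the percentage called lower, with edgeR adjusted p under 0.05. All 35 interferon-stimulated genes were higher with both agents than with R848 and all 35 lower with R848 than with IFN-α.

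Adding R848 to IFN-α raised cytokine, chemokine and NF-κB genes. Il1b went from 4.97 ± 2.10 CPM with IFN-α to 6092 ± 370.3 CPM with both agents, Tnf from 83.6 ± 14.2 to 8775 ± 796 CPM and Il6 from 13.7 ± 1.33 to 1517 ± 129.5 CPM. Interferon-stimulated genes differed less, with a median log2 fold change of 0.33, and Isg15 was 1.75-fold higher. The test called 3652 genes, 2035 higher and 1617 lower, with 765 and 482 differing at least 2-fold.

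Cytokine genes were higher in 17 of 18 (median 5.78, and the same with Il12b at its bound), chemokine genes in 17 of 21 with 1 lower (median 3.06) and NF-κB genes in 18 of 22 with none lower (median 2.38). Il12b was at least 701-fold higher. Il1b rose by 10.28 ± 0.16, Il1a by 9.31 ± 0.12, Cxcl2 by 9.74 ± 0.15, Cxcl1 by 8.40 ± 0.19, Il6 by 6.78 ± 0.14, Tnf by 6.71 ± 0.12 and Ccl5 by 6.48 ± 0.17. Csf3 and Csf2 rose 545-fold (95% counting interval 151 to 4506) and 157-fold (95% counting interval 27.8 to 6228). Nos2, with 3 counts over the IFN-α libraries and 4795 over the combined ones, gave a ratio of 1362-fold (95% counting interval 466 to 6609). Edn1, encoding the vasoconstrictor endothelin-1, rose by 7.12 ± 0.20, Traf1 by 6.27 ± 0.19, Ccl3 by 5.67 ± 0.11 and Cxcl10 by 1.75 ± 0.092. Ifnb1 had 2 counts over the IFN-α libraries and 13 over the combined ones, a ratio of 5.54-fold (95% counting interval 1.25 to 50.6).

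Oxidative and nitric oxide genes were higher in 15 of 19 and lower in 2 (median 1.74), with Ptges at 5.31 ± 0.13, Ptgs2 at 3.87 ± 0.13 and Irg1, which makes itaconate, at 3.72 ± 0.088. In the MHC class II and costimulation list 7 of 9 tested members were higher (median 1.74), with the costimulatory genes Cd40 at 4.08 ± 0.10 and Cd83 at 2.44 ± 0.096. The classical class II genes H2-Aa, H2-Ab1 and H2-Eb1 and their regulator Ciita were too low to be tested, and H2-DMa and H2-DMb1 were not called. Inflammasome and cell death genes were higher in 17 of 29 and lower in 6 (median 0.47), with Nlrp3 at 6.18 ± 0.14 and the survival genes Bcl2a1d and Bcl2a1b at 4.14 ± 0.13 and 3.05 ± 0.096, both uncertain because they are close copies. Interferon-stimulated genes were higher in 22 of 35 and lower in 1, with Ifih1 at 1.12 ± 0.086, Trim25 at 0.82 ± 0.097 and Rsad2 at 0.82 ± 0.08 (adjusted p = 0.160 for the list with an estimated correlation, and the list did not pass with library totals alone).

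Homeostatic microglia genes were lower in 15 of 22 and higher in 4 (median -0.53, adjusted p = 0.00125, or adjusted p = 0.116 with an estimated correlation). P2ry13 was at -3.28 ± 0.14, P2ry12 at -2.14 ± 0.20 and Tmem119 at -2.47 ± 0.64, while Gpr84 rose by 5.92 ± 0.15. Cx3cr1 was higher by 0.41 ± 0.11, a call that ended without IFN-α replicate 3 (adjusted p = 0.0602) and with library totals alone (adjusted p = 0.587). The genes that fell furthest were Abi3 (-6.23 ± 0.38), Gpr157 (-4.51 ± 0.16), the myeloid transcription factor Cebpa (-4.43 ± 0.13), Tmem86a (-4.37 ± 0.16), the cannabinoid receptor Cnr2 (-4.25 ± 0.51), the chemokine receptor Cxcr4 (-4.19 ± 0.14), Arhgap19 (-4.13 ± 0.22) and Gcnt1 (-3.85 ± 0.17). Gpr183 and Fgd2 had 1 count each over the combined libraries and IFN-α to combined ratios of 72.7-fold (95% counting interval 12.6 to 2919) and 54.0-fold (95% counting interval 9.21 to 2177). The combined level of Abi3 lay below the floor of a single library, so the size of its fall is uncertain. Tlr7 (624 ± 25.1 CPM with both agents) did not pass the test (adjusted p = 0.916). Ifnar1 was higher by 1.40 ± 0.093.

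Astrocyte markers were higher in 6 of 11 and lower in none (median 0.60, adjusted p = 0.160, or 0.0193 with no low-count filter and 0.0154 without R848 replicate 1 and combined replicate 3), with Aqp4 at 1.90 ± 0.18, Slc1a3 at 1.12 ± 0.16 and Gfap at 0.92 ± 0.19. Gfap was at 1213, 1838 and 1203 CPM in combined replicates 1, 2 and 3, and its call ended in a fit of these groups alone (adjusted p = 0.0539). Oligodendrocyte markers were higher in none and lower in 2 of 10, neuron markers higher in 1 of 6 and fibroblast markers higher in 3 of 11. The DESeq2 test did not call Sox10 (adjusted p = 0.107), Stmn2 (0.126), which is the neuron marker, or the fibroblast marker Lum (0.0671). Of the endothelial markers Kdr was lower (-2.56 ± 0.25) and Cdh5 higher (0.96 ± 0.18), and S100a8 was at 0.65 ± 0.26 (adjusted p = 0.0587).

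Camera called 14 of 23 lists against IFN-α, 13 up and 1 down, and 6 with an estimated correlation: cytokines, chemokines, NF-κB, MHC class II and costimulation, the oxidative list and inflammasome and cell death. The remaining calls had these adjusted p-values with an estimated correlation: adjusted p = 0.221 for Toll-like receptors (9 higher and 4 lower of 21, led by Irak3 at 3.74 ± 0.17), adjusted p = 0.0587 for interferon genes (12 and 0 of 18, led by Socs3 at 5.02 ± 0.16), adjusted p = 0.189 for MHC class I (10 and 1 of 19, led by H2-Q4 at 1.16 ± 0.09, which has close copies), adjusted p = 0.189 for glycolysis (7 and 2 of 21, led by Slc2a1 at 1.99 ± 0.12), adjusted p = 0.160 for immediate early genes (11 and 2 of 21, led by Dusp2 at 4.22 ± 0.25) and adjusted p = 0.103 for phagocytosis (11 and 4 of 17, led by C3 at 2.72 ± 0.097). Lists that did not pass had 5 higher and 9 lower of 21 for disease-associated microglia, 2 and 6 of 26 for cholesterol, 1 and 3 of 22 for oxidative phosphorylation, 1 and 3 of 15 for the cell cycle and 8 and 1 of 16 for the unfolded protein response. With no low-count filter 20 lists passed, adding disease-associated microglia (adjusted p = 0.0475), cholesterol (0.0256), the cell cycle (0.0430), the unfolded protein response (0.00818), astrocytes (0.0193) and fibroblasts (0.0296). With library totals alone Toll-like receptors (0.0623), MHC class I (0.107) and glycolysis (0.139) did not pass. The interferon genes list again had no tested gene encoding an interferon. Adjusted over the list alone, the higher and lower counts were the same except 22 and 2 for interferon-stimulated genes, 18 and 1 for chemokines, 19 and 0 for NF-κB, 9 and 5 for Toll-like receptors, 13 and 0 for interferon genes, 11 and 1 for MHC class I, 18 and 6 for cell death, 6 and 9 for disease-associated microglia, 13 and 2 for immediate early genes, 6 and 1 for astrocytes, 0 and 0 for neurons, 2 and 0 for fibroblasts and 1 and 0 for S100a8 as the sole leukocyte marker tested. The higher share of calls was 55.7% with TMM, 44.8% with upper-quartile factors and 21.7% with library totals alone, settings that moved the median of all genes by -0.083 and -0.31.

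Genes that stood above both single agents with the combined treatment included Nos2, the chemokine genes Cxcl9 and Cxcl11, Il27, Edn1 and the collagenase gene Mmp13. Nos2 (GRCm38 chromosome 11, 78920787 to 78960254) was at 469 ± 41.6 CPM with both agents against 17.2 ± 5.50 with R848 and 0.333 ± 0.319 with IFN-α. Cxcl9 (chromosome 5, 92321347 to 92328079) was at 1365 ± 135 CPM against 2.30 ± 0.734 and 59.1 ± 5.99, and Cxcl11 at 1383 ± 21.4 CPM, with log2 fold changes of 4.35 ± 0.14 against R848 and 5.14 ± 0.15 against IFN-α. Il27 (chromosome 7, 126589010 to 126594941) was at 366 ± 26.7 CPM against 2.93 ± 1.84 with IFN-α, Edn1 at 219 ± 17.8 CPM against 11.3 ± 2.82 and 1.51 ± 0.377, and Mmp13 at 6698 ± 424 CPM against 391 ± 24.3 and 259 ± 18.9. The receptor gene Slamf7 was at 786 ± 86.3 CPM against 19.4 ± 1.92 and 54.1 ± 6.93, and AA467197 at 102 ± 8.82 against 2.69 ± 1.03 and 7.62 ± 0.562. Mab21l3 and Heatr9 were near the floor with either agent alone and at 11.8 ± 1.54 and 8.42 ± 1.76 CPM with both. Il6 (adjusted p = 1.88e-21), Ccl5 (5.02e-12), Cxcl10 (3.50e-15), Isg15 (3.82e-09) and Tnf (1.45e-08) also passed the test against both.

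Fewer genes, 149, stood below both single agents. Chst10, a sulfotransferase gene, was at 3.43 ± 1.57 CPM with both agents against 29.5 ± 1.78 with R848 and 43.1 ± 6.31 with IFN-α, Cxcr4 (chromosome 1, 128588199 to 128592293) at 10.9 ± 2.14 CPM against 42.8 ± 6.86 and 209 ± 5.68, and Lhfpl2 at 24.0 ± 3.02 CPM against 101 ± 6.38 and 164 ± 16.9. Abi3 was at 0.403 ± 0.0292 CPM against 2.85 ± 1.67 and 33.0 ± 3.62. That combined level lay below the 0.603 to 1.30 CPM which a count of 0 in a single library allowed. The size of the Abi3 fall is therefore uncertain, and its small SD does not show precision. The glycosyltransferase genes B3gnt7 and B3gnt8, the potassium channel gene Kcnk6, and Mrgpre, Fam105a and Nfam1 completed the 10 named, with combined levels of 1.93 ± 0.661, 1.13 ± 0.272, 0.623 ± 0.589, 1.79 ± 0.463, 4.34 ± 1.32 and 3.67 ± 1.34 CPM.

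In all, 757 genes were higher and 149 lower than in both single-agent groups, with 199 and 37 differing at least 2-fold from each. Those 757 genes, picked for being higher there, held 27.1%, 23.2% and 24.1% of the gene counts in the combined libraries. In the single-agent libraries they held 11.2% to 13.2%. The balance depended on scaling, with 521 higher and 367 lower under upper-quartile factors and 216 and 1658 with library totals alone. The lower count was 98 with DESeq2, and 91, 86 and 75 when combined replicates 1, 2 and 3 were left out in turn.

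**Figure D4:**
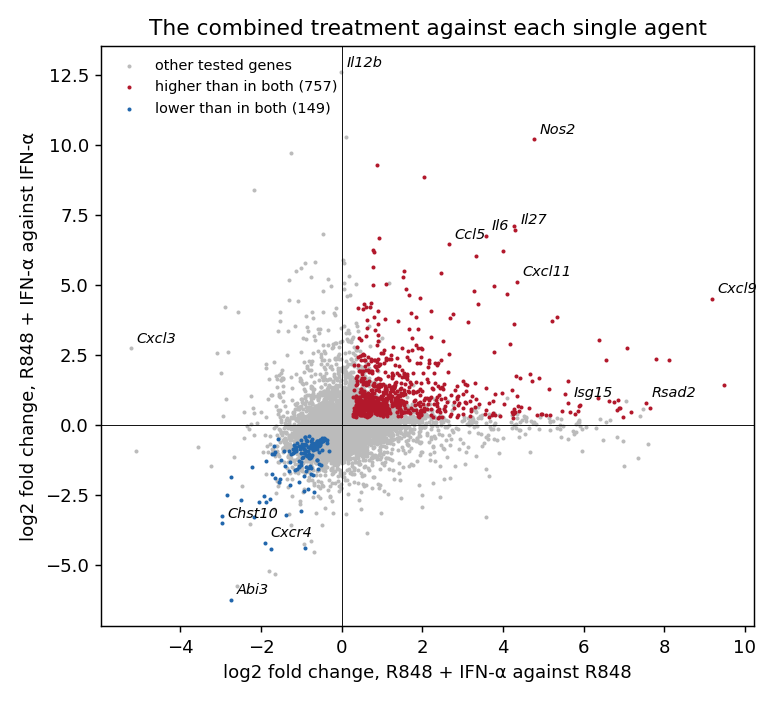
Each point is 1 of 11002 genes, with its log2 fold change in the combined treatment against R848 (horizontal) and against IFN-α (vertical), red where higher than in both (757) and blue where lower than in both (149), by edgeR. Cxcl9 lies at 9.19 and 4.53, Cxcl3 at -5.22 and 2.76, and Il12b, with no count in the IFN-α group, is drawn at its fitted value, which is no measured fold.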

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

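The tests of scaling, of the size of the falls, of depth, of abundant microglial transcripts and of astrocyte against oligodendrocyte markers were chosen after the results were seen, whereas those of NRF2 targets, further astrocyte transcripts and other splits of the libraries were set before their values were seen.

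Signal appeared in the forward-strand counts, a column that the comparisons in the results, made on reverse-strand counts, did not use. Whether the same reads were counted for other genes in the reverse-strand column was not checked. In total 7 genes had at least 100 forward-strand counts in each of the 9 libraries and more forward-strand than reverse-strand counts: AV051173, Gfm2, Tmem132a, Snx22, Sla2, Tsix and Zfp385c. AV051173 had 11247 forward-strand and 22 reverse-strand counts in all. No explanation was tested for these genes.

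More genes were higher than lower in the combined treatment relative to both single agents, at a ratio of 5.08. Unequal depth is argued against, since the ratio was 6.24 once all libraries were thinned to 1 depth. Scaling stays open, because the lowest ratio over 5 scalings was 0.130 for all calls and 0.317 for calls of at least 2-fold, both with library totals alone, so the balance may come from how the libraries were scaled. A biological explanation, that both agents together raise more genes than they lower, stays open too and cannot be settled without a measure of RNA per cell.

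The neutrophil-attracting chemokines Cxcl1 (-2.16 ± 0.086), Cxcl2 (-1.26 ± 0.079), Cxcl3 (-5.22 ± 0.20) and Cxcl5 (-2.82 ± 0.39) and the oxidative-stress genes Gclm, Hmox1, Srxn1 and Slc7a11 were lower with both agents than with R848, as log2 fold changes. Scaling is argued against by size: the smallest fall of these 8 genes less 2 standard errors was 1.10 (Cxcl2), and the 5 scalings tried differed by at most 0.41 in their shift of all genes. Fewer microglia as the whole cause of these falls is argued against by a median log2 fold change of 0.14 for 20 abundant microglial transcripts. Of these transcripts 7 were called higher and 6 lower, and the scaling itself can centre on such transcripts. Their median therefore does not measure the microglial share of the libraries. At the lowest over the scalings that median was -0.25 ± 0.12 (SE over the transcripts, taken as independent). A hypothesis is that IFN-α lowers the NRF2 programme, the transcription factor response to oxidative stress. In line with it, NRF2 targets outside the first lists were lower as a set (camera p = 0.00763, adjusted p = 0.0172), though not with an estimated correlation (p = 0.140, adjusted p = 0.304).

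Of 11 astrocyte markers 10 were called higher with both agents than with R848 and 6 than with IFN-α, though the list did not pass camera in either comparison (adjusted p = 0.136 and 0.160). Scaling as the whole cause is argued against for R848. There the median log2 fold change was 0.77 with TMM and at the lowest 0.40 with library totals alone. The standard error of the mean over members, taken as independent, was 0.073 in each and understates the error of a median. However, the calls fell to 5 with upper-quartile factors and 4 with library totals as the folds shrank, so the count of 10 is not kept. Against IFN-α the lowest median was 0.29 ± 0.22 (also the standard error of the mean), with members too spread to decide. Astrocyte and oligodendrocyte medians differed by 3.13 standard errors, taken from the spread over members as if these were independent. The inter-gene correlation was estimated at 0.22 and 0.099 for those lists, so these standard errors are too small. A lower microglial share that raises every other cell type alike therefore stays undecided. More astrocyte RNA in the combined libraries, or a response of astrocytes to both agents, may account for these values but stays open: the lower of both medians of further astrocyte transcripts was 0.46 with TMM, but 0.32 with upper-quartile factors and 0.058 with library totals alone.

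Other splits of the libraries were refitted for each count. With 3 libraries against 3 there are only 10 splits, too few for a share under 0.05. The real split called 3947 genes for the combined group against R848, 3652 against IFN-α and 4119 for R848 against IFN-α, and it was the only 1 of 10 as large in each. The highest other split called 0 genes with edgeR, and at an unadjusted p under 0.05 the other splits reached 478, 354 and 523 genes. No other tool was run on the splits. For lists the real counts were 10, 14 and 8, the highest others 10, 8 and 8, and the splits as large 2, 1 and 2. For the 3 groups together 1 of 100 drawn splits of the 9 libraries, the real one, reached 5534 genes, the highest other being 1401. That argues against groups that do not differ. For genes higher than in both, 1 of 300 splits with a designated group, the real one, was as large as 757 (highest other 671), a share under 0.05. The 300 are 3 designations of each of 100 splits and are not independent. They cannot decide whether the count is particular to the combined group, since the real groups with a single agent designated gave 586 and 671. For genes lower than in both, 10 of 300 were as large as 149 (highest other 1064). That share is under 0.05, but it is not taken to exclude chance, since other splits called several times as many. The counts of 671 and 1064 come from the real groups with a single agent set against the rest, and splits that mixed the groups reached 252 higher and 770 lower. Since mixed splits also passed the real 149, the lower count does not stand out by size. Groups that mix the treatments unequally still differ by treatment, so the larger counts do not point to any further structure of the samples.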

How the results depend on the processing

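Library totals alone, Rn45s left out, thinning to equal depth and leaving out a pair of libraries were chosen after seeing the data. No called gene changed sign in any alternative among the calls shared with the TMM fit. With library totals alone, 6157 genes were called for the combined group against R848, 1173 higher and 4984 lower, and against IFN-α 1044 higher and 3768 lower, with 216 higher and 1658 lower than in both single agents. Upper-quartile factors gave 2861 genes lower than with R848 and 367 lower than in both, and the DESeq2 test gave 1194 and 98. The cause was not tested for these. Without R848 replicate 1 and combined replicate 3 together, 3555 genes were called against R848, 3660 against IFN-α and 4301 between the single agents, with 827 higher and 123 lower than in both. Leaving out each library in turn gave 75 to 209 genes lower than in both. With an estimated inter-gene correlation 6 lists passed against R848 and 6 against IFN-α. Map2 against R848 reversed to -0.0081 with library totals alone (adjusted p = 0.970), where its adjusted p was 0.0239 with TMM and 0.0537 to 0.133 in 7 alternatives that ended its call. Over all counts, 305 of the alternative values stayed within 1.5 times, and 6927 of the named-gene values kept direction and side of the threshold while 117 no longer passed it and 2 newly passed it, Il12b and Ifnar1 against R848. DESeq2 values with no adjusted p stayed out of these counts.

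The replicate numbers in the titles did not pair the libraries: over 9 same-number pairs the correlation of deviations from group means ran from -0.10 to 0.059, none was over 0.1, and the closest library of another group had the same number in 4 of 18 cases. With the replicate block, 3995 genes were called against R848, 3701 against IFN-α and 4147 between the single agents, 5617 among the 3 groups, and 789 higher and 166 lower than in both, with 10, 14 and 9 lists, so no count moved by over 1.5 times.

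Small changes were often missed in the simulated counts, where 34.2% of 1.41-fold changes between the combined group and R848 were recovered. Depth, replicate number and spread were not varied there, so the simulation cannot tell which of them limited recovery. It changed 200 genes, whereas 3947 were called in the real comparison, so that share may not hold for the real data. Genes such as Ifnb1, Gpr183 and Fgd2, with 1 to 13 counts in a group, carry wide intervals.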

Other observations

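The lists and tests of this part were all added after the results of the report were seen, and the members named were picked after their values were seen. Guanylate-binding proteins, interferon-induced GTPases, were higher with both agents than with R848 in 10 of 10 (median log2 fold change 3.80, camera adjusted p = 5.59e-05 with an estimated correlation) and higher than with IFN-α in 8 of 10 (median 0.83, adjusted p = 0.0128). Gbp11 differed from R848 by 5.17 ± 0.17 and Gbp4 by 5.13 ± 0.11, and Gbp5 differed from IFN-α by 1.60 ± 0.08. Schlafen genes were higher in 7 of 7 against R848 (median 4.35) and in 6 of 7 against IFN-α (median 0.78), although these copies share sequence. PARP genes were higher in 9 of 12 against R848 (median 1.82), led by Parp12 (3.65 ± 0.096), and in 7 of 12 against IFN-α, where the list did not pass (adjusted p = 0.150).

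Chemokine and formyl peptide receptors were higher with both agents than with IFN-α in 5 of 6 (median 2.93, adjusted p = 0.0128 with an estimated correlation). The formyl peptide receptors Fpr1 and Fpr2 were at 5.51 ± 0.16 and 3.94 ± 0.17, and Cxcr3 at 3.54 ± 0.59. That list left out the chemokine receptor Cxcr4, which was lower with both agents than with IFN-α (-4.19). Against R848, Fpr1 was lower at -1.12 ± 0.097 and Ccrl2 higher at 2.46 ± 0.094, and the list did not pass (adjusted p = 0.136). Purinergic receptors other than P2ry12 and P2ry13, which the homeostatic list holds, moved both ways, 2 higher and 3 lower of 9 against R848 and 4 and 4 against IFN-α, with P2ry14 at 3.91 ± 0.32 against R848 and at -0.99 ± 0.18 against IFN-α. Metalloproteinases and their inhibitors, in a list without Mmp13, which stood above both single agents, were higher in 3 of 14 and lower in 1 against R848, and higher in 8 and lower in 2 against IFN-α (adjusted p = 0.116). NRF2 targets were higher with R848 than with IFN-α in 16 of 21 and lower in 1 (median 0.50, adjusted p = 3.41e-04, or adjusted p = 0.0990 with an estimated correlation), with Osgin1 at 1.97 ± 0.37 and Gsr at 1.68 ± 0.11, and 12 of 21 were lower and 4 higher with both agents than with R848. Further astrocyte transcripts were higher in 14 of 21 in each comparison of the combined group, with adjusted p = 0.0932 against R848 and 0.0115 against IFN-α, the latter lost at adjusted p = 0.156 with an estimated correlation. Abundant microglial transcripts were higher in 7 and lower in 6 of 20 against R848 and higher in 6 and lower in 10 against IFN-α.

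Among 282 genes tested on forward-strand counts that exceeded their reverse-strand counts, 56 differed between the combined group and R848, 62 between the combined group and IFN-α and 90 between the single agents, by edgeR over those genes alone. No explanation was tested for them.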
